A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

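Two-colour microarrays compared RNA from zymolyase-treated and untreated cells of a *mid2* mutant of *Saccharomyces cerevisiae* in the BY4741 background. Per the labels' protocols, each culture was grown in rich medium at 24 °C and divided, and 1 part received zymolyase at 0.8 units per ml for 3 h. The labels describe 2 cultures, each hybridised in both dye orientations, which makes 4 arrays. Treated RNA was in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. The labels do not say which arrays share a culture, and they differ from the design text on how long the refreshed cultures grew before the division.

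The deposited values are 1 number per open reading frame (ORF) and array, taken here as a log2 ratio of the 2 channels. The base of the logarithm, the numerator and the authors' normalization are not given in the sources used here, and scanner intensities were not used here. The table held 6209 rows, of which 2 were control rows that were left out. Values were present for 4708, 3585, 4790 and 4965 ORF rows on arrays 1 to 4, and 24.2%, 42.2%, 22.8% and 20.0% of the rows were blank. The arrays' medians over these rows were 0.04, −0.40, −0.13 and −0.08, and their median absolute deviations were 0.47, 0.57, 0.50 and 0.23. Array 4 therefore had the narrowest spread. Spot brightness over background is unknown, and the number of arrays limits the precision.

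ORF names were matched to the locus tags of a RefSeq gene table (assembly R64), used for names only. Of the 6207 ORF rows, 5654 matched a locus tag, 57 matched a synonym held by a single gene, and 496 matched neither and kept the name in the table. Rows of 1 gene were averaged (34 genes had several rows), which left 6172 genes. Tests used the 3299 genes (53.5%) with a value on all 4 arrays. No coordinates are given because the table names no genome build.

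Pearson correlations between arrays, taken across genes, which are not independent replicates, were above 0 for every pair (0.13 to 0.48). Between orientations they were 0.39 for arrays 1 and 2 and for arrays 3 and 4, against 0.14 for arrays 1 and 4 and 0.13 for arrays 2 and 3, which does not by itself show which arrays share a culture. By the rule fixed before the data were examined, arrays of opposite dye orientation were therefore taken as already turned the same way. Rank correlations support this less: Spearman values were 0.41 and 0.39 within an orientation, but 0.14, 0.04, −0.04 and −0.08 between orientations. The sign was set from 10 anchor genes known to be induced by zymolyase, whose median was above 0 on every array. Positive values are thus called likely higher in treated cells, and the anchor genes give no independent evidence of that direction.

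The main test used limma 3.58.1 in R 4.3.3. Each array with treated RNA in Cy3 can share a culture with either array with treated RNA in Cy5, so there are 2 possible pairings. Under each pairing the 2 arrays of a culture were averaged. This cancels a dye effect that is equal and opposite in the 2 orientations, and no other. The 2 culture means were tested against 0 with lmFit and eBayes (1 residual degree of freedom). A gene was called only if its Benjamini-Hochberg adjusted p was under 0.05 under both pairings, and the larger p and standard error were kept. The estimated prior degrees of freedom were unlimited under the pairing of arrays 1 with 2 and 12.7 under the pairing of arrays 1 with 4. For that reason nearly every gene had the same standard error of 0.28 (range 0.28 to 0.42), and genes whose arrays disagree can still be called. Errors printed with gene means are therefore the SD over the 4 arrays. A separate rule of size described genes with a mean change of at least 2-fold and the same direction on all 4 arrays.

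Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of these lists, 34 had at least 3 measured members and were tested with camera (limma, preset correlation 0.01) under both pairings, with the larger p kept and adjusted over the lists. Lists were also tested with an estimated correlation and with fry, both on the 4 arrays with a dye term, which leaves 2 residual degrees of freedom. Even the anchor list did not pass there (adjusted p = 0.259 for camera with an estimated correlation and 0.0638 for fry). A list that fails these tests is therefore not shown to be unchanged. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and in the same direction on all 4 arrays. It also named up to 4 members of each described list with the largest change, *MID2*, *HOG1* and the anchor genes. Any other gene named was chosen after its values were seen, and the text says so.

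The procedure was tested on simulated data for the 3299 genes of this comparison, with 200 genes changed. With cultures simulated as arrays 1 with 2 and 3 with 4, it recovered 80.6% of genes changed by 1 on the log2 scale, 97.0% at 1.5 and 100% at 2, and 20.3% of its calls were unchanged genes. With cultures simulated as arrays 1 with 4 and 2 with 3, it recovered 85.1%, 100% and 100%, and 4.52% of its calls were unchanged genes. Among simulated calls in the same direction on all 4 arrays the shares were 20.5% and 4.71%, so that restriction did not lower them. Of 200 random lists of 30 genes, 1% had a camera p under 0.05. These lists were drawn from the data simulated with arrays 1 with 4 as a culture, in which genes varied independently. The rate therefore does not cover lists of genes that vary together.

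The alternatives were centring each array, centring and scaling to 1 spread, values on at least 3 arrays, the median of a gene's rows, leaving out each array, each pairing alone, 4 arrays as replicates with or without a dye term, a robust variance prior and other thresholds. With an array left out of the main test, the remaining array of its culture stood alone for that culture. It thus weighed more than each other array, and its dye effect was not cancelled. Gene means printed without an array are averages of the culture means over both pairings, not plain means of the remaining arrays. The rule of size used plain means. After the data were seen, counts restricted to genes in the same direction on all 4 arrays were added, alone and with the robust prior.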

Results

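Zymolyase is an enzyme preparation that digests the glucan of the yeast cell wall, and Mid2 is a plasma membrane sensor of the cell wall integrity pathway. The 4 arrays compared *mid2* mutant cells after 3 h of zymolyase with untreated cells of the same cultures, to describe the transcriptional response of cells without this sensor. No array of cells with intact *MID2* was analysed here, so the values describe the response of the mutant alone. *MID2* itself had no value on any of the 4 arrays, which leaves the genotype unchecked. *HOG1* was read because a comment label of the untreated channel of array 4 names a *hog1* mutant, and its log2 ratios were 0.20, 0.55, −0.15 and 0.26 on arrays 1 to 4. All values below are log2 ratios of treated over untreated cells in the likely direction, with the SD over 4 arrays of 2 cultures.

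After 3 h of zymolyase, part of the cell wall protein and general stress genes of *mid2* cells rose, and a few genes each for purine synthesis, phosphate acquisition and iron uptake fell. As groups, 9 of 34 gene lists passed with camera at a preset correlation, but 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 0 with fry (10 unadjusted). Of 3299 genes tested, 137 passed the threshold (limma, both culture pairings), and 104 of these moved in the same direction on all 4 arrays, 66 of them up and 38 down. The largest rise was that of *HSP12*, a small stress protein of membranes, at 3.37 ± 0.71 (SD over 4 arrays of 2 cultures), or 10.3-fold (adjusted p = 2.37e-07). *RTC3* rose by 3.07 ± 0.78 and *KDX1*, which encodes a paralog of the cell wall integrity kinase Slt2, by 3.04 ± 1.31. The largest falls were those of *SER3*, which encodes a serine biosynthesis enzyme, at −2.21 ± 2.01, and *TIR3*, a cell wall mannoprotein gene of oxygen-poor growth, at −2.08 ± 1.95. Single arrays carried much of both means, since *TIR3* read −2.70, −0.68, −4.56 and −0.39 on arrays 1 to 4 and *SER3* was lowest on array 3. Without array 3 the averages of the culture means were −1.24 for *SER3* and −1.07 for *TIR3*, which then did not pass (limma, adjusted p = 0.0611).

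The 10 largest rises also included *CWP1* at 2.72 ± 0.08 and *SED1* at 2.61 ± 0.80, both of which encode major cell wall mannoproteins. *PIR3*, another cell wall protein gene, rose by 2.51 ± 0.43 and *YPS3*, which encodes a cell surface aspartyl protease, by 2.22 ± 0.78. *NFG1* (2.71 ± 0.82), the stress gene *DDR2* (2.55 ± 0.61) and *YPL088W* (2.25 ± 0.89) completed the group. Among the 10 largest falls were *FIT2* (−1.81 ± 0.99) and *FIT3* (−1.55 ± 1.22), which encode cell wall mannoproteins that retain siderophore iron, and *ENB1* (−1.41 ± 0.74), a siderophore transporter gene. The others were the multidrug efflux gene *ATR1* (−1.57 ± 1.08), *YKL030W* (−1.53 ± 0.98), the acid phosphatase gene *PHO11* (−1.47 ± 1.12), the flavohemoglobin gene *YHB1* (−1.47 ± 0.67) and *AGA2* (−1.30 ± 0.41), which encodes the adhesion subunit of a-agglutinin. The adjusted p-values of these 20 genes lay between 2.37e-07 and 0.000778. Each of the 10 largest falls was lowest on array 3, though *FIT2* only narrowly (−2.69, against −2.62 on array 1). Without array 3 the averages of the culture means of *FIT3*, *ATR1* and *PHO11* were −0.92, −1.02 and −0.90.

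**Figure D1:**
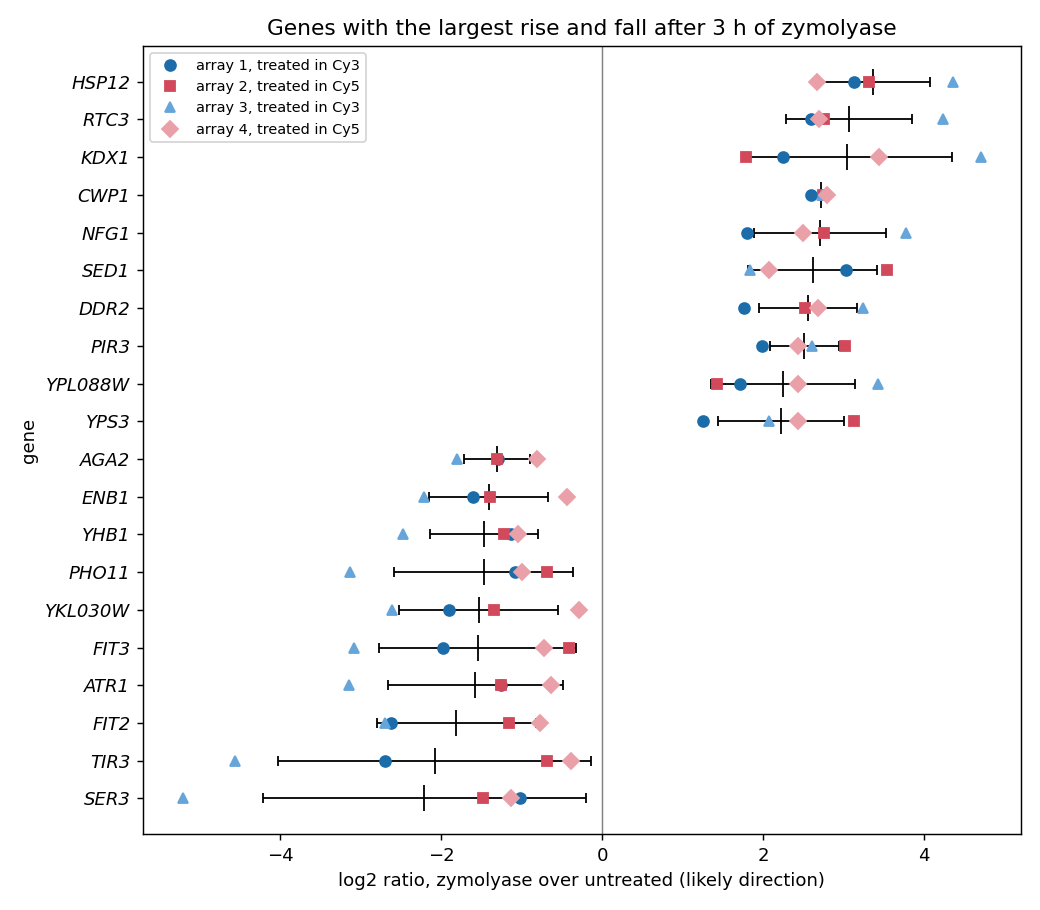
Log2 ratio of treated over untreated cells (x axis, likely direction) for the 10 genes with the largest mean rise and the 10 with the largest mean fall (y axis) among genes past the threshold and in the same direction on all 4 arrays. Coloured points are single arrays, the black tick is the mean and the bar its SD. *CWP1* lay between 2.60 and 2.79 on the 4 arrays, while *SER3* stood at −5.21 on array 3 and between −1.48 and −1.02 on the others.

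Of the 10 anchor genes of the core cell wall stress response, 9 rose, also when adjusted over the list alone, and the list was used to set the direction of the ratios. Besides *KDX1*, *CWP1*, *SED1* and *PIR3*, these were *NCW2* (2.15 ± 0.50), *SLT2* (2.00 ± 0.67), *PRM5* (1.76 ± 0.25), *PST1* (1.54 ± 0.31) and *CRH1* (1.47 ± 0.42). *SLT2* encodes the MAP kinase of the cell wall integrity pathway, and *CRH1* encodes an enzyme that links chitin to glucan. The glucan synthase gene *GSC2*, also called *FKS2*, did not pass, with values of 1.31, −1.57, 1.57 and 0.07 on arrays 1 to 4. It passed only without array 2, where the average of its culture means was 1.10. The camera test placed the list above the other genes (adjusted p = 7.77e-26), but not with an estimated correlation (adjusted p = 0.259).

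Of 35 other measured genes for cell wall proteins and wall remodelling, 11 rose, 5 fell and 19 did not pass, against 13 risen and 5 fallen when adjusted over the list alone. *YPS3*, *PUN1* (1.77 ± 1.19), *SPI1* (1.72 ± 0.80) and the yapsin gene *YPS1* (1.17 ± 0.69) were among the risen. Those that fell were *TIR3*, *FIT2* and *FIT3*, with *CRR1* and *PLB2*, the last pair named after their values were seen and not in the same direction on all 4 arrays. *FIT2* and *FIT3* also belong to the list of iron genes. The list median lay 0.41 above that of all genes (camera, adjusted p = 8.29e-05), the adjusted p was 0.333 with an estimated correlation, and the call was lost without array 2.

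Genes for the synthesis of glucan, chitin and mannan rose in 4 of 31 cases, or 5 adjusted over the list alone, and none fell. *OCH1*, which starts the outer mannan chain of N-glycans, rose by 1.40 ± 0.34. *GFA1* (1.23 ± 0.30) and *PCM1* (0.90 ± 0.30) act in the supply of the chitin precursor UDP-N-acetylglucosamine, and *KRE6* (0.88 ± 0.44) acts in β-1,6-glucan synthesis. The list median was 0.34 above that of all genes (camera, adjusted p = 2.21e-05, and adjusted p = 0.259 with an estimated correlation).

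Osmostress target genes rose in 9 of 14 cases, or 11 adjusted over the list alone, and none fell. After *HSP12*, the leading members were *GPD1* (1.67 ± 0.13), which encodes the first enzyme of glycerol synthesis, the aldehyde dehydrogenase gene *ALD3* (1.54 ± 0.31) and *MSC1* (1.53 ± 0.22). Of 24 genes of the general stress response driven by Msn2 and Msn4, 7 rose, or 11 adjusted over the list alone, and none fell. This list shares *HSP12*, *ALD3* and *MSC1* with the osmostress list, and *DDR2* and *SPI1* were among its other risen members. The medians of the osmostress and general stress lists were 1.11 and 0.63 above that of all genes (camera, adjusted p = 6.21e-19 and 1.32e-16), and the adjusted p was 0.265 for both with an estimated correlation.

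Trehalose and glycogen genes rose in 3 of 13 cases, or 5 adjusted over the list alone, and none fell. *TPS2* (1.52 ± 0.47) and *TSL1* (1.39 ± 0.39) encode subunits of the trehalose synthase complex and *GSY2* (0.95 ± 0.28) encodes a glycogen synthase, while *PGM2*, at 0.84 ± 0.33, did not pass. The list median was 0.65 above that of all genes (camera, adjusted p = 5.21e-07, and adjusted p = 0.259 with an estimated correlation).

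Purine and one-carbon genes fell in 5 of 18 cases, or 10 adjusted over the list alone, and none rose. *ADE1* (−1.07 ± 0.38) and *ADE8* (−1.01 ± 0.51) encode enzymes of purine synthesis, *SHM2* (−0.93 ± 0.31) encodes a serine hydroxymethyltransferase and *GCV1* (−0.92 ± 0.31) a subunit of glycine decarboxylase. The list median was −0.63, against −0.14 for all genes (camera, adjusted p = 5.67e-06, and adjusted p = 0.350 with an estimated correlation).

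In the phosphate regulon 4 of 12 genes fell, or 5 adjusted over the list alone, and none rose. *PHO11* and *PHO12* (−1.10 ± 0.36) are near-identical acid phosphatase genes that these spots may not tell apart, and *PHM6* (−1.17 ± 0.29) and *SPL2* (−0.88 ± 0.40) were the others. The list median was −0.59 (camera, adjusted p = 0.000203, and adjusted p = 0.475 with an estimated correlation). In the iron regulon 3 of 10 genes fell, namely *FIT2*, *FIT3* and *ENB1*, and the same 3 when adjusted over the list alone, while the permease gene *FTR1* did not pass at −0.43 ± 0.62. Each of the 3 read lower on both arrays with treated RNA in Cy3 than on either with it in Cy5. Their half-differences between orientations (treated in Cy5 minus Cy3) were 0.84, 0.98 and 0.50. The median over the 38 falls in 1 direction was 0.38. The iron list mean was −0.55 and its median −0.22, so the shift rested on those few genes (camera, adjusted p = 0.0341, and adjusted p = 0.475 with an estimated correlation). The iron call was lost without array 1 or array 3, with genes on at least 3 arrays and without a dye term.

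The 38 falls in the same direction on all 4 arrays were deeper where treated RNA was in Cy3 (median −1.45) than where it was in Cy5 (median −0.91), whereas the 66 rises had medians of 1.37 and 1.39. By array, the medians of the falls were −1.13, −1.19, −1.78 and −0.64 on arrays 1 to 4. As deposited, the gap between these medians thus lay between arrays 3 and 4, and not between arrays 1 and 2. The medians of all genes tested were −0.02, −0.37, −0.04 and −0.07 on arrays 1 to 4, so array 2 was lower as a whole. After each array was centred on its median, the falls' median half-difference between orientations (Cy5 minus Cy3) was 0.47, against 0.38 as deposited. Arrays 1 and 2 thus cannot be compared by the deposited medians alone.

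**Figure D2:**
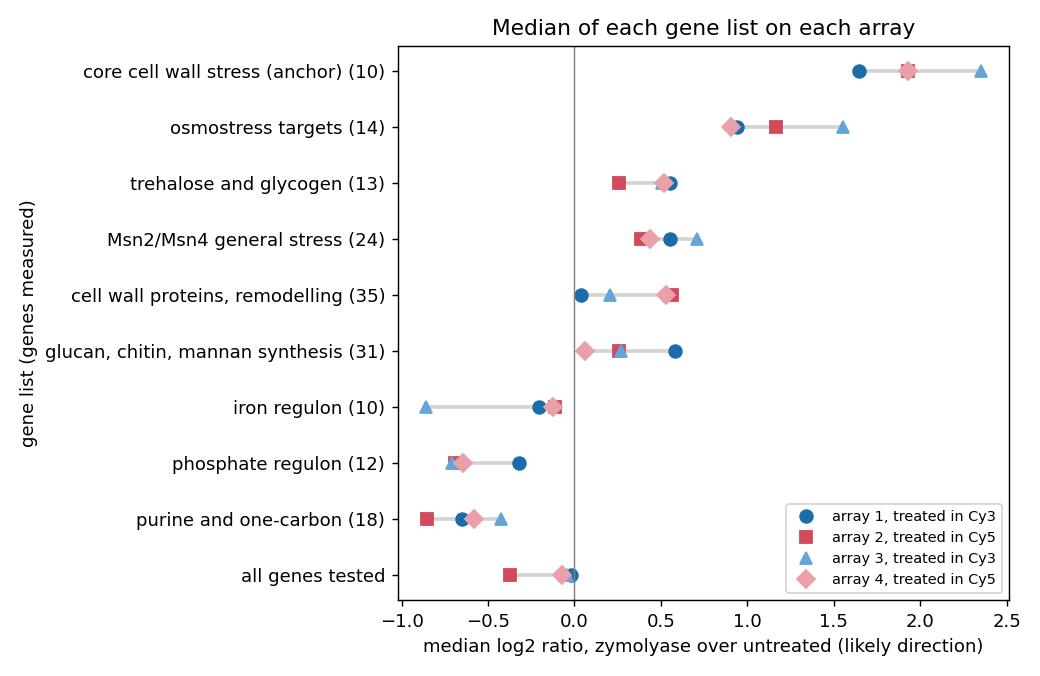
Median log2 ratio of treated over untreated cells (x axis, likely direction) on each of the 4 arrays for the 9 gene lists past the camera threshold and for all 3299 genes tested, with the number of measured genes in brackets (y axis). Points are arrays and the grey line joins the lowest and highest. The medians of the anchor list, used to set the direction, lay between 1.65 and 2.35, and those of the purine and one-carbon list between −0.85 and −0.43.

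The other 25 lists tested did not pass with camera in the main comparison. In 12 alternatives that kept the preset correlation, the list of the TCA and glyoxylate cycles passed upward in 8, calcineurin targets and respiration upward in 7 each, Gcn4-dependent genes downward in 6 and histones downward in 1. Of 39 Gcn4-dependent amino acid synthesis genes 3 fell, which were *SER3*, *HIS4* (−1.15 ± 0.96) and *HIS3* (−1.68, −0.50, −1.66 and −0.18 on arrays 1 to 4), a gene carried as a deletion allele in BY4741 (list adjusted p = 0.0598). The glucose transporter gene *HXT1* rose by 2.16 ± 0.34, the only call among 12 hexose transport genes, and the osmosensor gene *MSB2* rose by 1.23 ± 0.85, the only call among 9 genes of HOG signalling. *YPS1* was the only call among 8 calcineurin targets and *NDE1* (0.86 ± 0.37) the only one among 31 respiration genes. *DDR48* rose (1.44 ± 0.71) in the list of pheromone and filamentation genes, where *AGA1* also passed although its arrays disagreed (−0.56, 0.16, −4.86 and −0.64). None of 128 ribosomal protein genes, 44 ribosome biogenesis genes, 49 mitochondrial ribosomal protein genes, 29 proteasome genes or 20 heat shock chaperone genes passed. The same held for 9 histone genes, 17 genes of glycolysis and fermentation, 20 of ergosterol synthesis, 14 of methionine synthesis and sulfate assimilation and 14 of the TCA and glyoxylate cycles, and for the lists of G1/S genes (15), G2/M genes (7), RNA polymerases I and III (15) and autophagy (7). Over the 388 genes of these 14 lists, 16 had an unadjusted p under 0.05 in the limma test, and 1 passed on 4 arrays with a dye term. The list of the TCA and glyoxylate cycles held 5 of the 16 and that 1 gene. Adjusted over each list alone, 2 genes of that list and 1 of glycolysis and fermentation passed upward, as did 2 pheromone and filamentation genes, 2 oxidative stress genes passed downward, and no respiration gene passed. *ATR1* was the only call among 16 oxidative stress genes, *AGA2* among 6 a-specific genes and *PIR1* (0.93 ± 0.36) among 12 genes of daughter cell separation.

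Of the 137 calls, 33 were not in the same direction on all 4 arrays, and 12 of these were rows of Ty retrotransposons. The 11 rows of TYA, the Gag part of the element, had medians of 3.17 and 3.84 on arrays 1 and 2 but 0.37 and −0.29 on arrays 3 and 4. *HAC1* (1.67, 3.32, 0.23 and −0.10), from the list for the unfolded protein response, and *TUS1* (1.41, 3.18, −0.20 and −0.16), from the list for cell wall integrity signalling, passed with values above 1 on arrays 1 and 2 alone.

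**Figure D3:**
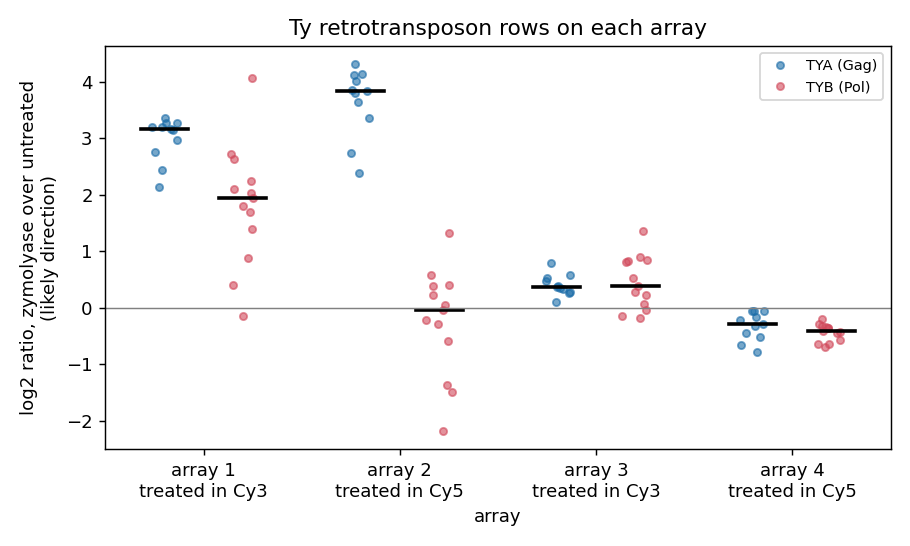
Log2 ratio of treated over untreated cells (y axis, likely direction) of 11 TYA rows and 13 TYB rows on each of the 4 arrays (x axis). Points are rows, which are near-identical copies and not independent, and black lines are medians. TYA medians were 3.17 and 3.84 on arrays 1 and 2, and 0.37 and −0.29 on arrays 3 and 4.

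By size alone, 75 genes changed by at least 2-fold on average in the same direction on all 4 arrays, 49 up and 26 down, and all 75 were among the 137. Nearly every gene had the same standard error, so the threshold was itself close to a rule of size. The overlap was thus largely fixed in advance and is no separate support. Without the rule on direction 100 genes reached 2-fold. A half-difference of at least 1 in size was reached by 9 genes between dye orientations. Between arrays 1 and 2 and arrays 3 and 4 it was reached by 41, and between arrays 1 and 4 and arrays 2 and 3 by 2. It is a log2 difference of at least 2 between the means of the 2 array pairs, a wider gap than 2-fold. The count of 137 (91 up, 46 down) fell to 5 without array 4, 47 without array 1 and 73 without array 2, and to 2 (2 up, 0 down) when arrays were scaled to 1 spread. With 2 cultures, and arrays whose culture is not stated, the gene calls rest on a spread borrowed across genes.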

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

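The test for a sample that stands apart was fixed before the data were examined, and no explanation was weighed here. For each of 59 named genes, the gap between the farthest array and its neighbour was set against the range of the 4 arrays and compared with Dixon's critical value for 4 samples. In 7 genes 1 array stood apart, and in 6 of them it was array 3. Chance flags about 5% of groups of independent samples, or 2.95 of 59, but that rate does not hold here: the arrays are dye swaps of 2 cultures with unequal spreads, and many of the genes were named for extreme means, which a single array can produce.

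*SER3* read −5.21 on array 3, and −1.02, −1.48 and −1.14 on arrays 1, 2 and 4. *AGA1* read −4.86 on array 3, with −0.56, 0.16 and −0.64 on the others, so its fall rested on that array. *PHO11* read −3.13 on array 3, against −1.08, −0.69 and −0.99, and its near-identical copy *PHO12* read −1.58 there. *HIS4* stood at −2.58 and *YHB1* at −2.47 on array 3, while their other arrays lay between −0.83 and −0.58 and between −1.22 and −1.05. *RTC3* stood at 4.24 on array 3 and between 2.59 and 2.76 on the others. *PST1* was lowest on array 1, at 1.07, with 1.65 to 1.73 on the others.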

How the results depend on the processing

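All alternatives here except the restriction to 1 direction were chosen before the data were examined. The 4 arrays, the unstated culture of each and the unknown spot brightness limit every count, and of 55 named genes past the threshold only *SED1* kept its call in every setting. For genes past the threshold (137, 91 risen and 46 fallen), centring the arrays gave 115, 28 of them fallen, 94 shared with the 137, and moved the median of all genes by 0.13. Centring with scaling to 1 spread gave 2 (2 risen, 0 fallen, against 396 and 164 fallen at an unadjusted limma p under 0.05), values on at least 3 arrays 47 (44 and 3), arrays 1 with 4 as the only pairing 306 (156 and 150), arrays 1 with 2 as the only pairing the same 137, and 4 arrays without a dye term 65 (53 and 12). A dye term gave 125 calls, 101 of them shared. Restricting the calls to 1 direction left 104 (66 and 38), and 148 (83 and 65) with a robust prior. Without that restriction fallen genes numbered 74 with a robust prior, 28 at an adjusted p under 0.01 and 72 under 0.1. Leaving out single arrays gave 5 to 101 calls (4 to 83 risen, 1 to 25 fallen), with the lowest count, 5, without array 4 (47 without array 1, 73 without array 2). At an unadjusted p under 0.05, 357 genes passed.

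The 75 genes of at least 2-fold in 1 direction (49 up, 26 down) became 216 (100 and 116) at 1.5-fold and 30 (28 and 2) when each array had to reach 2-fold. Leaving out single arrays gave 75 to 122 (49 to 73 up, 21 to 49 down), with 122 without array 4, where fewer arrays had to share a direction.

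Of the 9 lists past the threshold (6 up, 3 down), 0 passed with an estimated correlation (0 up, 0 down) and 0 with fry (0 up, 0 down), while 5 and 10 of the 34 lists had an unadjusted p under 0.05. Scaling gave 14 lists, 5 of them down, with all 9 among them, and leaving out single arrays gave 9 to 10 (6 to 8 up, 2 to 4 down). *GSC2*, at 0.34 and not past the threshold, turned to −0.17 without array 1 and −0.24 without array 3, and passed at 1.10 without array 2. These are averages of culture means, in which a lone array counts as a culture. The sign without array 1 rests on that weighting. Over the alternatives, 223 of 767 values of named genes lost the threshold in the same direction, and 106 of these came from leaving out an array. Taking the median of a gene's rows changed none of these counts, but only 34 genes had several rows, so little could change. For the other changes named here the cause was not tested.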

Other observations

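Except for the *HOG1* reading, all tests in this part were chosen after the values were seen, and genes outside the fixed lists were picked after their values were seen. Other genes among the 38 falls in 1 direction were the following, and they were not tested as a group. *ZRT1* (−1.15 ± 0.77, SD over 4 arrays; limma, adjusted p = 0.00131) and *ZRT2* (−0.94 ± 0.72, adjusted p = 0.021) encode zinc transporters, and the copper metallothionein copies *CUP1-1* (−0.95 ± 0.45) and *CUP1-2* (−0.99 ± 0.36), which cannot be separated by sequence, fell alike. The sulfite pump gene *SSU1* fell by 1.25 ± 0.44 (adjusted p = 0.00034).

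Among 1130 genes with values on exactly 3 arrays, which were not tested in the main comparison, 8 averaged at least 2-fold up and 9 at least 2-fold down in 1 direction. Array 2 was the blank one in 921 of the 1130. The highest means were those of *CRG1* (2.25 ± 0.70, SD over 3 arrays), *PRM10* (2.08 ± 0.52) and *AFR1* (2.02 ± 0.67). *PTP2*, which encodes a phosphatase of the MAP kinases Hog1 and Slt2, averaged 1.23 ± 0.42. *ARG1* averaged −1.35 ± 1.02.

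TYA rows stood far above 0 on arrays 1 and 2 and near 0 on arrays 3 and 4. The dye contrast of a row is the half-difference between orientations, treated in Cy5 minus treated in Cy3. Dye bias is argued against by the TYA rows' median dye contrast of 0.039 (SD 0.10), beside a median half-difference of 1.73 between the array pairs. A full-length Ty RNA higher in the treated cells of 1 culture would carry TYB as well and stays open: the TYB median was 1.95 on array 1, only 1.22 below that of TYA (SD of TYB rows 1.07), but −0.05 on array 2, where TYA stood at 3.84, and probe positions are not given. Outside the Ty rows, 29 genes also had a half-difference of at least 1 in size between these array pairs, against 2 for arrays 1 and 4 against arrays 2 and 3. A difference between the array pairs other than dye, such as culture or hybridisation session, is a candidate explanation, and the labels do not say which.

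Averaged over the arrays of each orientation, falls read deeper with treated RNA in Cy3. Their dye contrast was above 0 in 29 of 38 genes (median 0.38) against 33 of 66 rises (median 0.00). As deposited, the median of the falls on array 1 (−1.13) was not below that on array 2 (−1.19), while arrays 3 and 4 stood at −1.78 and −0.64. Array 2 was lower as a whole, however. After each array was centred on its median, the falls' median dye contrast was 0.47. The narrower scale of array 4 is argued against as the whole cause, since after scaling the falls kept a median dye contrast of 0.33 (SE 0.07 over genes), although that of the rises then stood at 0.31. The 38 genes share the same 4 arrays, so this SE does not measure variation between arrays. The falls were also called before scaling. Dye-dependent readings of dim spots may contribute: 7 genes deleted or silent in this strain, from the fixed lists without *CLB1*, which dividing cells express, and *HIS3*, itself among the 38 falls, had a median dye contrast of 0.40, above that of 99.98% of 10000 random sets of 7 genes (99.99% with both, 9 genes). *LEU2*, deleted in BY4741, averaged −1.05 with treated RNA in Cy3 and 0.03 in Cy5, and the values of *LEU2*, *RED1* and *MF(ALPHA)2* had been seen before this test was chosen. Over the 4 arrays *LEU2*, *RED1* and *MF(ALPHA)2* averaged −0.51, −0.41 and −0.79. None of them passed the threshold, but averaging the orientations did not bring them to 0. Of 23 such genes listed, only the 7 had values in both orientations, and only those seen before had values on all 4 arrays. The others, *DMC1* (0.40), *IME1* (0.11), *SAG1* (0.73) and *SMK1* (−0.15), were blank on array 2 and were not ranked alone. The random sets were drawn from all 4901 genes with a value in both orientations and were not matched for such blanks. Array 2 read lower than array 4 as a whole (medians −0.37 and −0.07), so a blank there can raise a gene's dye contrast. The percentile may therefore be too high. *SAG1* read −2.66 on array 3 but −0.05 on array 1. Brightness of the fallen genes' spots is unknown, and a true fall in both orientations stays open.

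A comment label of the untreated channel of array 4 names a *hog1* mutant, while its genotype label says *mid2*. If that RNA lacked *HOG1*, the ratio on array 4 would be far above 0. It was 0.26 there, within the range of the other arrays (−0.15 to 0.55) and below 1 by more than the SD of 0.29 over the 4 arrays. The reading and its direction were fixed before the data were seen, but the bound of 1 was set after. *MID2* had no value on any array, so the genotype itself was not tested.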
